A study of Octopus bimaculoides with 16 samples.

How the data were processed

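Bulk messenger RNA was sequenced from dissected tissues of the California two-spot octopus, Octopus bimaculoides. Per the labels' protocols, tissues were dissected by hand, RNA was extracted with phenol and chloroform, and libraries were made with the Kapa mRNA HyperPlus kit. The labels list 16 samples, which are 8 libraries on 2 sequencing lanes each. The libraries came from 7 tissues. The whole sucker cup had 2 libraries, labelled automated and manual, both from the arm named R1. Dissociated cells of sucker rims, optic lobe (a part of the brain), eye, olfactory organ, mantle skin and statocyst (the balance organ) had 1 library each. The title of the rim cell library names 8 suckers and no arm. What automated and manual refer to is not given in the sources used here, nor whether these are separate suckers or separate preparations of the same RNA.

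The submitters' processing notes name Trim Galore, a read trimmer, and kallisto, which assigns reads to transcripts; the genome build, annotation and tool versions are not given in the sources used here. The deposited table holds 15842 genes under National Center for Biotechnology Information LOC identifiers and has 1 column per library, so the lanes of a library were already merged, by a method that is not given. Its values are log2(CPM + 1), where CPM is read counts scaled to a library total of 1000000, a unit read from the deposited values themselves. After inversion each column summed to 1000000 over all rows, and every value in each column was a whole multiple of the value of 1 read (100% of values within a tolerance of 0.01 reads). Reads per gene and library totals were recovered from these multiples. Estimated counts from kallisto need not be whole, so the deposited counts may have been rounded or made another way, which is not given, and intervals and floors treat them as reads. The plan fixed before the data were examined had assumed depth-normalised values on a linear scale, and the deposited log2 values were inverted to CPM to follow it. Every column already summed to 1000000, so rescaling changed nothing.

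Library totals ran from 4782744 reads in mantle skin and 5373482 in optic lobe to 36916825 in the sucker rim cells. A single read was worth 0.209 CPM in mantle skin and 0.0271 CPM in the rim cells. Shares of reads carry 95% Wilson intervals, CPM values of single libraries have exact 95% Poisson intervals, and ratios of reads, which have no pseudocount and pool the reads of both whole sucker libraries, carry exact 95% Clopper-Pearson intervals. A value of 0 was set to a floor of 3 reads per library where a ratio was given, and the ratio was then written as a lower bound at that floor. The exact 95% lower limit of the ratio to a named tissue, which allows for more than 3 reads, lies below it and is given beside it. The reads carry no stated molecular identifiers, so intervals and floors cover counting error only, not variation between animals, dissections or libraries.

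With 1 library for every tissue except whole sucker cup, no significance test was made between tissues. A gene was called higher in a tissue when log2(CPM + 1), with a pseudocount of 1 CPM, was at least 4-fold above the highest of the tissues compared and the gene had at least 10 CPM in the higher tissue. Ratios on this scale understate changes of low genes. Ratios, levels and shares of called genes come from the same values that selected them, so their direction between the compared tissues follows from the rule. The whole sucker cup entered as the mean CPM of its 2 libraries. It was compared with the 5 non-sucker tissues, and each non-sucker tissue was compared with the other 6 tissues. For rim cells against whole sucker cup, a gene had to pass against both whole sucker libraries. The automated and manual libraries were first compared by a chi-square of their reads per gene over 12001 genes with at least 20 reads, to see whether they were separate libraries. Similarity of libraries was measured as Pearson and Spearman correlations across the 14783 genes with a read in any library. The remaining 1059 rows held no read.

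Gene names were sought in a reference table of the assembly ASM119413v2. Of the 15842 identifiers, 14305 were found there and 1537 were not. The table gives no functional name for these genes, and only 2 identifiers have a synonym, so the 24 gene lists fixed as name patterns before the data were examined, including that of nicotinic acetylcholine receptor-like subunits, were not applied. In that case the rule fixed beforehand names at most 2 identifiers per direction and comparison, those with the largest log2 ratio. The 2 genes with a synonym were added after the values were available. The build behind the deposited values is not given, so positions are not stated, and the table's gene order was used only to see which measured genes neighbour each other on its chromosomes (13929 genes).

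Alternatives fixed beforehand were pseudocounts of 0.1 and 5 CPM, no floor or a floor of 50 CPM, and median-of-ratios size factors. Also fixed beforehand were leaving out either whole sucker library and the ratio to the mean log2(CPM + 1) of the non-sucker tissues. Correlations over genes with at least 10 CPM in any library were fixed beforehand too. Thinning of all libraries to 4782744 reads, a lower 95% counting bound of at least 4-fold, and comparison with only the non-sucker tissues were added after seeing the data. Reads of all 15842 genes were also simulated for the whole sucker comparison. The rule recovered 100 of 100 genes planted at 8-fold and 0 of 100 planted at 3-fold, and called 0 of 15642 unchanged genes. All simulated libraries shared the same mean profile with counting noise only, and folds were planted in genes with a mean of at least 10 CPM. These counts check the working of the rule and are not error rates for real tissues. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

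Reads of near-identical gene copies can be divided between them when they are assigned, so the value of any gene with close copies is uncertain. No sequence was used here to identify such copies.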

Results

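RNA was measured in sensory organs of Octopus bimaculoides and in tissues for comparison. The sucker cups with which an octopus touches and tastes surfaces were sequenced whole, and cells dissociated from sucker rims were sequenced apart. Eye, olfactory organ, statocyst, optic lobe and mantle skin completed the set of 7 tissues. The 2 whole sucker libraries, automated and manual, held 11830859 and 8293516 reads. The rim cell library was the deepest, with 36916825 reads. Optic lobe had 5373482 reads, eye 12241705, olfactory organ 14264654, mantle skin 4782744 and statocyst 15167497. Tissues other than whole sucker cup had no replicate. The labels give arm R1 for both whole sucker libraries and name no animals, so no difference between tissues could be set against variation between animals. Values are read counts scaled to a library total of 1000000 (CPM), recovered from the deposited log2(CPM + 1). Intervals are 95% intervals of counting error only.

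The number of genes with at least 10 CPM ranged from 6299 in optic lobe to 8533 in statocyst. A common set of 4864 genes reached 10 CPM in all 7 tissues, of 11139 that did so in any. Within that common set, 3118 genes varied by less than 4-fold over the 7 tissues and 733 by less than 2-fold. The 10 most abundant genes took 21.9% of the reads of optic lobe, against 5.81% in statocyst, 6.25% in olfactory organ and 7.16% in rim cells. A single gene held 6.57% of the optic lobe reads.

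The first comparison placed the tissues beside each other. The whole sucker cup was about equally similar to rim cells (Pearson's r = 0.937 for the automated library) and to mantle skin (r = 0.937), and less so to olfactory organ (r = 0.889). The order of rim cells and mantle skin depended on the measure. Spearman's rho was 0.938 with rim cells and 0.944 with mantle skin for the automated library, and 0.939 and 0.942 for the manual library, whose Pearson's r was 0.938 and 0.935. Olfactory organ and mantle skin were also close (r = 0.924). Eye, optic lobe and statocyst had lower correlations with these tissues, and not uniformly high ones with each other. Eye reached r = 0.774 with optic lobe and 0.762 with statocyst, while the automated whole sucker library reached 0.705 with eye, 0.652 with optic lobe and 0.612 with statocyst. Optic lobe correlated with statocyst at 0.681, below its values with olfactory organ (0.707) and mantle skin (0.696), and eye reached 0.743 with olfactory organ. These correlations are across 14783 genes, which are not independent replicates. The automated and manual libraries correlated at 0.995 (Spearman's rho 0.995). They differed by more than sampling noise, with a median chi-square per gene of 0.855 against 0.455 by chance, and were kept as 2 libraries. Whether they are separate suckers or repeat preparations of the same RNA is not given in the sources used here, so their spread may be technical only. Among 7833 genes with at least 10 CPM, 95% differed between them by less than 1.28-fold, 8 differed by over 2-fold and 3 by over 4-fold.

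**Figure D1:**
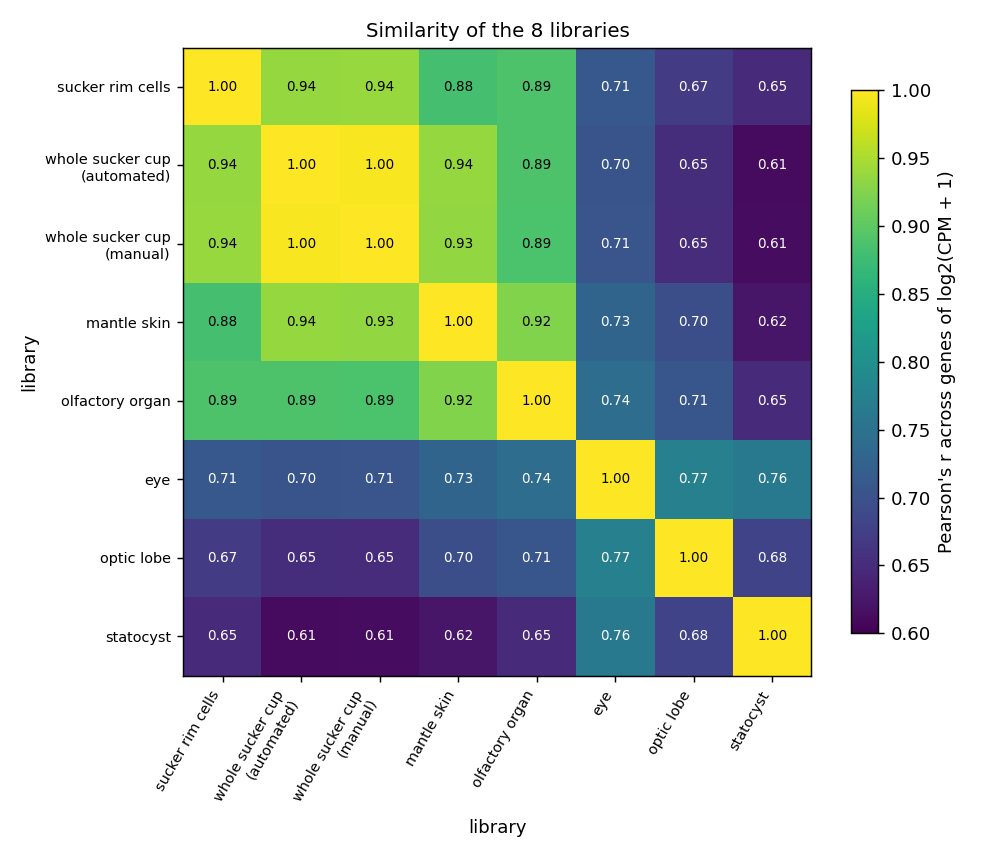
Pearson correlation across genes of log2(CPM + 1) for each pair of the 8 libraries, printed in each cell and shown by colour. Whole sucker cup, rim cells, mantle skin and olfactory organ have high values with each other, and the lowest value is 0.612, between statocyst and the automated whole sucker library.

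The whole sucker cup was then compared with the 5 non-sucker tissues. In the whole sucker cup, 119 genes were at least 4-fold higher than in every non-sucker tissue. Their median log2 ratio to the highest of these tissues was 5.35, 81 genes exceeded 16-fold, and 47 exceeded 64-fold. For 54 of the 119, all 5 non-sucker tissues lay under 1 CPM. Many were abundant, with 67 at 100 CPM or more and 23 at 1000 CPM or more. The 119 genes together took 15.4% of the reads of the automated library (15.39 to 15.43%) and 15.04% of the manual library. They took 6.17% of the reads of rim cells, 0.0681% in olfactory organ, 0.0643% in mantle skin, 0.0243% in eye, 0.0162% in statocyst and 0.00361% in optic lobe. Low shares in the 5 non-sucker tissues follow from the selection, which used these same libraries.

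On the log2(CPM + 1) scale by which genes were ranked, the highest ratio, 12.95, belonged to LOC106882233, the most abundant gene of both whole sucker libraries. It reached 33187 CPM in the automated and 32374 CPM in the manual library, and 1764 CPM in rim cells. Mantle skin, the next tissue, had 15 reads of it (3.14 CPM), a ratio without pseudocount of 10475 (6351 to 18715). LOC106869022 had 13722 and 13687 CPM in the whole sucker libraries, 8569 CPM in rim cells and 4 reads in mantle skin, a ratio without pseudocount of 16390 (6401 to 60156) and a log2 ratio on that scale of 12.87. The difference between the automated and manual values of either gene was below 1.28-fold. Measured against the mean log2(CPM + 1) of the non-sucker tissues instead of the highest, the count rose from 119 to 818 genes. Tissues without reads lower such a mean, so a gene can pass while 1 non-sucker tissue is as high as the sucker.

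Genes shared by whole sucker cup and rim cells were examined next. Both kinds of sucker sample passed against every non-sucker tissue for 94 genes, with a median log2 ratio of 5.89 in whole sucker cup. Rim cells by themselves passed for 167 genes, so that 25 genes passed the rule against non-sucker tissues in whole sucker cup but not in rim cells, and 73 the reverse. These groups do not by themselves measure a difference between the sucker samples. Compared directly, 126 of the 167 genes passed neither 4-fold rule between rim cells and whole sucker cup, 25 were higher in rim cells and 16 were lower. Of the 119 whole sucker genes, 80 passed neither rule, 33 were lower in rim cells and 6 were higher. Thus some genes that passed in whole sucker cup alone were also directly lower in rim cells. Likewise, some that passed in rim cells alone were directly higher there. LOC106873015 had 4238 and 4150 CPM in the whole sucker libraries and 6212 CPM in rim cells. In the non-sucker tissues it had a single read, in statocyst. Its ratio to statocyst was 63730, with an interval from 11438 to 2517220. This interval does not cover mantle skin and optic lobe, which had no read but are shallower libraries. The upper counting limit of the gene was 0.771 CPM in mantle skin and 0.686 CPM in optic lobe, against 0.367 CPM in statocyst. Its ratio to either of those tissues may therefore lie below 11438. The 94 genes took 14.9% and 14.6% of the reads of the whole sucker libraries and 6.15% of those of rim cells. With a floor of 50 CPM, 55 of the 94 genes passed.

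**Figure D2:**
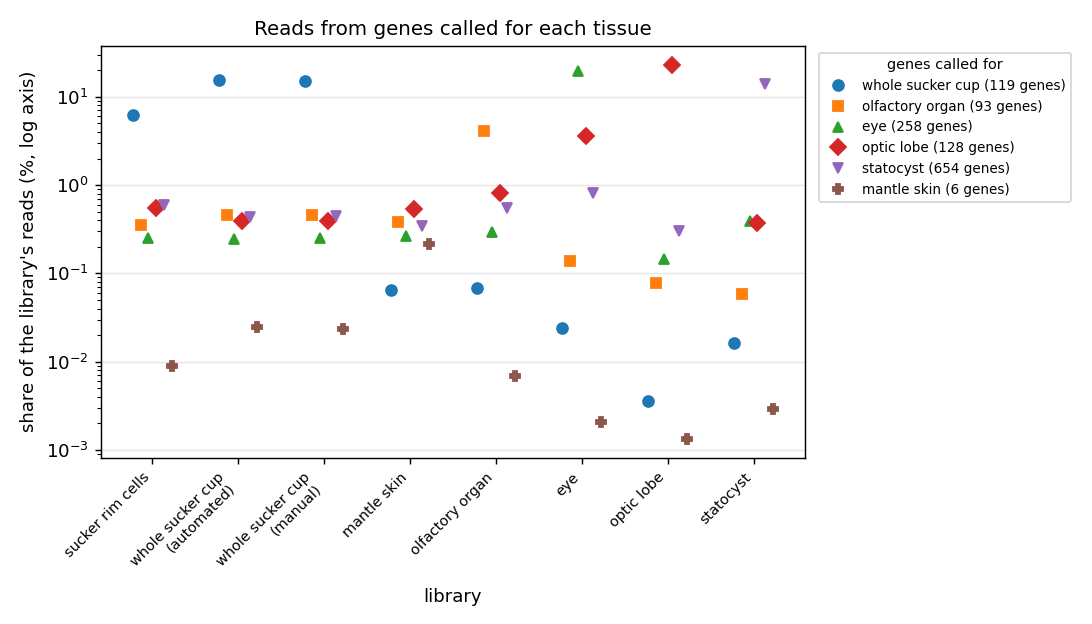
Share of each library's reads (percent, log axis) from the genes called for whole sucker cup, olfactory organ, eye, optic lobe, statocyst and mantle skin, with 1 point per gene set and library. The 119 sucker genes took 15.4% and 15.04% of the whole sucker libraries and 6.17% of rim cells, against at most 0.0681% elsewhere. Each set was selected on these same libraries, so its low shares in the tissues it was compared with follow from the rule.

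Rim cells were also compared directly with the whole sucker cup. Of 8690 genes with at least 10 CPM in either, 261 were at least 4-fold lower in rim cells than in both whole sucker libraries and 74 were higher. A whole cup includes its rim, which can limit how far a gene stands higher in rim cells but not how far it stands lower. The counts and sizes of both directions are therefore not like measures. The median log2 ratio of the lower genes was -3.86, 119 of them exceeded 16-fold, and 90 lay under 1 CPM in rim cells. They took 12.9% and 12.6% of the reads of the whole sucker libraries and 0.777% of those of rim cells. Of the 261 genes, 213 had at least 10 CPM in mantle skin and 121 in olfactory organ, while 33 lay under 1 CPM in mantle skin. The share with at least 10 CPM in mantle skin, 81.6%, was below that of all 7833 genes with at least 10 CPM in whole sucker cup, 93.9%. LOC106881506 had 723 and 717 CPM in the whole sucker libraries and 9 reads (0.244 CPM) in rim cells, a ratio of 2956 (1557 to 6465). It was also low in mantle skin, with 1 read. LOC106869401 had 585 and 547 CPM in the whole sucker libraries and 723 CPM in mantle skin, and no read in rim cells. From the pooled reads of the 2 whole sucker libraries, it was thus at least 7003-fold higher than the 3-read floor of the rim library, and the exact 95% lower limit of the ratio was 5695.

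The 74 genes higher in rim cells had a median log2 ratio of 2.34 and took 1.54% of the reads of rim cells, against 0.232% and 0.227% of the whole sucker libraries. At least 10 CPM was reached by 40 of them in olfactory organ, 35 in mantle skin, 34 in eye, 29 in statocyst and 16 in optic lobe, and 8 lay under 1 CPM in all 5 non-sucker tissues. LOC106868721 had 551 CPM in rim cells against 30.8 and 35.2 CPM in the whole sucker libraries, a ratio of 16.9 (15.6 to 18.3), and at most 3 reads in any non-sucker tissue. LOC106879789 had 121 CPM against 4.40 and 9.16 CPM, a ratio of 19.0 (15.9 to 22.8). Among the 119 genes of the whole sucker cup, 33 were lower in rim cells, 6 were higher and 80 passed neither rule. With median-of-ratios size factors the split of 74 higher and 261 lower became 39 higher and 295 lower, and with a pseudocount of 5 CPM 30 genes were higher. A floor of 50 CPM left 43 higher and 148 lower, and a lower counting bound of at least 4-fold left 42 higher. The rim library differed from the whole cups in the part of the sucker taken and in dissociation. It may also differ in the suckers used, since its title names 8 suckers and no arm while the whole cups came from arm R1.

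**Figure D3:**
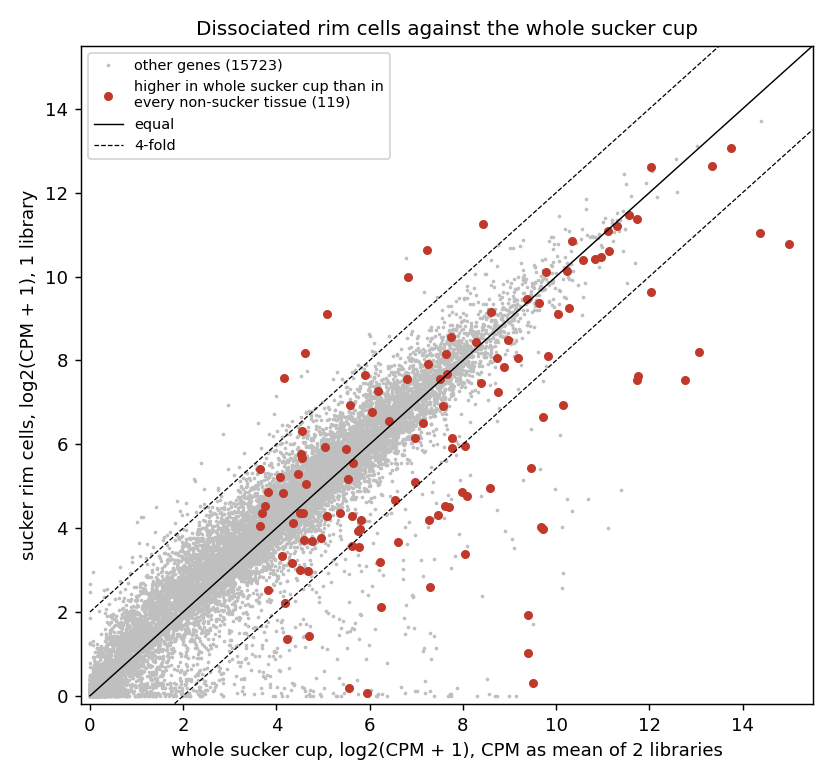
Expression in sucker rim cells (1 library) against whole sucker cup (mean CPM of 2 libraries), both axes log2(CPM + 1), with 1 point per gene, the 119 sucker genes in red, a solid line at equal values and dashed lines at 4-fold. Of the 119, 33 lie at least 4-fold lower in rim cells and 6 at least 4-fold higher than both whole sucker libraries.

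Each of the other tissues was compared with all remaining tissues. The eye had 258 genes at least 4-fold higher than everywhere else, with a median log2 ratio of 4.65. For 95 of them all other tissues lay under 1 CPM, and 88 exceeded 64-fold. They took 19.4% of the eye reads and at most 0.393% of the reads of any other library, in statocyst. Statocyst was the highest other tissue for 105 of them. LOC106878312, the most abundant gene of the eye, reached 26960 CPM against 2.97 CPM in statocyst, a ratio of 9087 (6791 to 12459). LOC106869775 reached 5309 CPM in the eye and had no read in any other library, at least 8463-fold above the 3-read floor of the shallowest library. The exact 95% lower limit was computed for its ratio to optic lobe, where it was 7733, and not for mantle skin, the shallowest library. The limit against mantle skin would be lower, as the 95% upper limit of 0 reads was 0.771 CPM there and 0.686 CPM in optic lobe.

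The reference table gives a name to LOC106873941, OTX, a homeobox transcription factor gene of head and brain development in animals. This gene and the hedgehog gene below were chosen for their names after the values were available. OTX had 94.3 CPM in eye (89.0 to 99.95) and 29.9 CPM in statocyst (27.2 to 32.8), a ratio of 3.15 (2.83 to 3.52) that did not reach 4-fold. With median-of-ratios size factors its log2 ratio of 1.62 became 2.001, just past that threshold. Olfactory organ had 3.08 CPM of OTX, rim cells 1.44 CPM and optic lobe 3 reads.

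The statocyst had the most genes of its own. In all, 654 genes were at least 4-fold higher there than in every other tissue, with a median log2 ratio of 3.33, and for 108 of them all other tissues lay under 1 CPM. Most were of moderate level, with 24 at 1000 CPM or more, and together they took 14.1% of the statocyst reads. Eye was the highest other tissue for 248 of these genes and rim cells for 170. LOC106873202 reached 5342 CPM against 1.30 CPM (7 reads) in optic lobe, a ratio of 4100 (1990 to 10199). LOC106881037 reached 726 CPM against 0.735 CPM in eye, a ratio of 987 (520 to 2159). The hedgehog gene LOC106871116, which encodes a secreted signalling protein, had 13.1 CPM in statocyst (199 reads) and 1.72 CPM in eye (21 reads), a ratio of 7.65 (4.87 to 12.6). It had at most 4 reads in any other library. Its log2 ratio of 2.38 fell to 1.43 with a pseudocount of 5 CPM, below the threshold. With a floor of 50 CPM, 409 of the 654 statocyst genes passed.

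In the optic lobe, 128 genes were at least 4-fold higher than in every other tissue, and these took 23.1% of its reads. They took 3.62% of the reads of the eye, which was the highest other tissue for 102 of them, and at most 0.804% of the reads of any further library. No optic lobe gene lay under 1 CPM in all other tissues, and the median log2 ratio was 2.26. LOC106867091 had 235 CPM against 13.3 CPM in eye, a ratio of 17.7 (15.01 to 20.9), and LOC106870704 had 400.1 CPM against 25.4 CPM, a ratio of 15.7 (14.0 to 17.8). With median-of-ratios size factors 311 genes passed, including all 128.

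The olfactory organ had 93 such genes, with a median log2 ratio of 2.81, which took 4.13% of its reads. All other tissues lay under 1 CPM for 13 of them. The highest other tissue was rim cells for 25 genes, mantle skin for 23 and whole sucker cup for 20. LOC106875191 had 437 CPM against 2.65 CPM in rim cells, a ratio of 165 (135 to 203). LOC106884259 had 418 CPM against 4.09 CPM in optic lobe, a ratio of 102 (67.4 to 163). Compared with the other non-sucker tissues only, 159 genes passed.

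Mantle skin had 6 genes at least 4-fold higher than in every other tissue, and they took 0.217% of its reads (0.213 to 0.221%). Whole sucker cup was the highest other tissue for 4 of them and olfactory organ for 2. LOC106867894 had 1891 CPM in skin against 206 and 194 CPM in the whole sucker libraries, a ratio of 9.41 (9.07 to 9.77). LOC106875139 had 65.0 CPM against 7.36 CPM in olfactory organ, a ratio of 8.83 (7.06 to 11.1). A pseudocount of 5 CPM left 3 genes, and comparison with the other non-sucker tissues only gave 149.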

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

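The thinning, counting-bound and non-sucker comparisons were chosen after the main counts were seen. Settings were varied for the 9 planned counts only: whole sucker cup, both sucker kinds, higher and lower in rim cells, and the 5 non-sucker tissues. None of these changed by more than 1.5 times when either whole sucker library was left out. The same held without a floor, with a pseudocount of 0.1 CPM, and with all libraries thinned to 4782744 reads. Other gene counts in the text were not repeated under these settings. Other settings moved some counts further, and the cause was not tested unless stated. A floor of 50 CPM, which admits fewer genes by construction, gave 55 genes for both sucker kinds, 43 higher and 148 lower in rim cells, and 409 for statocyst. A pseudocount of 5 CPM, which shrinks ratios of low genes, gave 30 genes higher in rim cells and 3 for mantle skin. Median-of-ratios size factors gave 39 genes higher in rim cells and 311 for optic lobe. These factors shifted all log2 values of optic lobe by 0.47, statocyst by -0.39, olfactory organ by -0.23, rim cells by -0.11 and the whole sucker libraries by 0.16 and 0.12 relative to CPM, which moves the counts of those tissues. Requiring a lower counting bound of at least 4-fold gave 42 genes higher in rim cells. The ratio to the mean log2(CPM + 1) of the non-sucker tissues, a weaker demand, gave 818 genes for whole sucker cup. Comparison with the other non-sucker tissues only, fewer tissues to exceed, gave 159 genes for olfactory organ and 149 for mantle skin. Over the 11144 genes with at least 10 CPM in any library, the automated whole sucker library correlated at 0.995 with the manual library, 0.900077 with rim cells, 0.90006 with mantle skin and 0.356 with statocyst. Rim cells and mantle skin changed order in similarity to the whole sucker cup between Pearson and Spearman correlations of all genes. The values as deposited already summed to 1000000, so that setting changed nothing and tested nothing. Lanes could not be left out because the table has 1 column per library, and settings of the gene lists were not run because the reference table holds no functional names to match the lists. No paired analysis was possible because each tissue except whole sucker cup has 1 library and lanes are not replicates. Depth limits low genes most in mantle skin, where 3 reads are 0.627 CPM, and optic lobe, where they are 0.558 CPM.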

Other observations

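The tests of neighbouring genes (for their ratios, the criterion also was revised after the values were seen), of genes shared with mantle skin and of region against dissociation were chosen after the results were seen, as were the surface gene group and its shares; the thinning tests were added after the main counts were seen, and the size-factor test was chosen before.

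A large group of genes was shared by 4 tissues, whole sucker cup, rim cells, olfactory organ and mantle skin. In each of these, 405 genes were at least 4-fold higher than in each of optic lobe, eye and statocyst. Of the 35 ways of choosing 4 of the 7 tissues, the next highest gave 8 genes. Many of these ways part whole sucker cup from rim cells of the same organ, so low counts there say little. The reverse set, higher in optic lobe, eye and statocyst, held 36. The 405 genes took 19.2% of the reads of mantle skin, 15.99% in olfactory organ, 14.0% and 13.9% in the whole sucker libraries and 12.8% in rim cells. They took 0.497% in eye, 0.202% in statocyst and 0.179% in optic lobe. Their median level was 148 CPM in mantle skin, 144 in olfactory organ, 125 in whole sucker cup and 114 in rim cells, against 4.003 in eye, 0.791 in statocyst and 0.186 in optic lobe. The genes were selected on these same values, so the direction of these differences follows from the selection. Another 108 genes were at least 4-fold higher in both whole sucker cup and mantle skin than in rim cells, optic lobe, eye and statocyst. These took 2.18% and 2.15% of the reads of the whole sucker libraries and 2.18% of mantle skin, but 0.0413% of rim cells, a direction that their selection also set. Eye and statocyst together exceeded all other tissues by 4-fold for 193 genes.

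Some genes called for the same tissue lay side by side in the gene order of the assembly ASM119413v2, counted over measured genes, with 25.2% of the placed sucker genes (those of whole sucker cup or rim cells), 25.7% of the eye genes, 22.3% of the statocyst genes, 17.4% of the olfactory genes and 12.9% of the optic lobe genes next to another of their set. Sucker genes formed 24 neighbour pairs, eye genes 40 and statocyst genes 83, while the highest of 10000 gene sets matched on mean expression held 9, 17 and 46, so random placement of genes of like expression does not account for them; the smaller olfactory and optic lobe sets had 8 pairs each, against at most 5 and 7. Neighbours were not particular to genes called for a single tissue. The 261 genes lower in rim cells formed 40 pairs, against at most 13, with 32.4% of placed genes next to another. For the 405 genes shared by 4 tissues there were 60 pairs, against at most 20, with 30.4%. LOC106869022 began a run of 5 sucker genes that held 3.61% of the whole sucker reads. LOC106869775 lay in a run of 9 eye genes at 77.2 to 5820 CPM in eye and at most 0.428 CPM elsewhere. Reads of 1 gene counted under its neighbours stay open as an explanation: the ratio of a pair changed by at least 2-fold beyond counting error between 2 libraries in 12 of 23 sucker pairs with 20 reads of each gene in both, 4 of 9 eye pairs and 32 of 57 statocyst pairs. Shared reads cannot be told apart from separate expression by these changes, because the labels name no animals and sequence variants between animals could also shift how reads divide between copies.

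For the 261 genes lower in rim cells than in whole sucker cup, 253 genes passed with every library thinned to 4782744 reads, 250 of them among the 261. The rim library was the deepest, so low depth could hardly make genes lower there, and thinning tested little. A few genes taking most of the counts did not account for the 261 genes, as 295 genes passed with median-of-ratios size factors, including all 261. Of the 261, 33 lay under 1 CPM in skin (12.6%, against 1.40% of all 7833 genes with at least 10 CPM in whole sucker cup). At least 10 CPM in skin was reached by 81.6% of the 261 genes, against 93.9% of those 7833. Neither share speaks for loss of cell kinds that the sucker shares with mantle skin, though such a loss may still contribute. Whether it is the whole cause cannot be decided from these values, because genes of a shared cell kind that is rarer in skin could also lie under 1 CPM there. The part of the sucker taken and the dissociation of the cells cannot be told apart, because the 1 rim library differs from the whole cups in both. The suckers used may differ as well and cannot be separated from these. The title of the rim library names 8 suckers and no arm, and the whole cups came from arm R1.

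Only 6 genes were called for mantle skin against 93 to 654 for olfactory organ, eye and statocyst. Low depth does not account for this, as the lowest of the counts for those 3 tissues was 93 after thinning to the depth of the skin library. Of 795 genes at least 4-fold higher in skin than in optic lobe, eye and statocyst, 785 were less than 4-fold lower in whole sucker cup, 633 in rim cells and 646 in olfactory organ. Olfactory organ had 842 genes at least 4-fold higher than in optic lobe, eye and statocyst, and 93 called against all tissues. These counts restate which tissues share the genes and do not test why.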
